A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

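The values analysed were the read counts per gene deposited by the authors, 1 column for each of 12 libraries. Per the labels, the authors extracted total RNA with phenol and chloroform, treated it with DNase, removed ribosomal RNA with Ribo-Zero Gold and made stranded TruSeq libraries. The submitters' notes name TopHat2 2.0.14 for alignment to sacCer3, SAMtools 0.1.19, HTSeq 0.6.1p1 for counting and DESeq2 1.8.1. The strand setting of the counting and the annotation used are not stated in those notes. All 12 columns were matched to a sample label and used.

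The 4 groups had 3 libraries each. Per the labels, they were wild type BY4741 with the vector pRS313-HA3-SSN6, a taf14 deletion strain with that vector, the deletion strain with the same vector carrying TAF14, and the deletion strain with it carrying the W81A form. All 4 labels include HA3-SSN6. They are called wild type, deletion strain, TAF14 strain and W81A strain. Libraries held 9.01 to 11.7 M counts. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples.

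Gene identifiers were matched by locus tag to the R64 (sacCer3) annotation. Of 6692 gene entries, 6008 matched, of which 6005 were protein coding and 3 were pseudogenes. The 684 unmatched entries held 0.952% of all counts. They stayed in the fit, where 254 were tested, and were not named. Near-copy genes were searched with blastn 2.17.0+, and 196 tested genes had another gene matching at least 30% of their length at 95% identity or more. Reads of such genes cannot be assigned with certainty. Because the strand setting is not stated, this also holds for genes overlapping another on either strand, which the 196 may include. Among named genes the near-copy doubt applies to RPL7B, SSA2 and AAD3, and the overlap doubt to GLK1, SER3, BNA2, COX2, RPL7B and PHO84.

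Differences were tested in R 4.3.3 with edgeR 4.0.16, by the quasi-likelihood F-test on 1 model with the 4 groups as terms and all 12 libraries. Scaling was by trimmed mean of M-values, and genes with too few counts were removed with the default filter, which left 5918 tested genes and removed 774. Residual degrees of freedom were 8, and the biological coefficient of variation was 8.59%. Adjusted p-values were by Benjamini-Hochberg within each comparison, and a gene was called where this was below 0.05. Log2 fold changes are given ± standard error, derived from the F statistic, and CPM (counts divided by the scaled library size, per 1e6) as mean ± standard deviation over n = 3 libraries. Where 0 reads were counted, up to 3 counts remained possible, which was at most 0.327 CPM, in the library with the smallest scaled size, and this limit covers counting error only. Non-overlapping genes were those where all 3 libraries of 1 group lay on 1 side of the other 3. With 3 against 3 libraries, chance alone gives this for 10% of unchanged genes.

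There were 39 gene lists, fixed before the data were examined, and each list with at least 5 tested members was tested with camera from limma 3.58.1 at its preset correlation between genes of 0.01. This covered 37 lists. The alpha-specific list had 4 tested members and no test, and the small nucleolar RNA list had 0 entries among the counted genes. Adjusted p-values for lists were by Benjamini-Hochberg over the 37 lists of a comparison. The test was repeated with the correlation estimated from the libraries. Then only 1 list call in the 6 comparisons held, the lower heat shock chaperones of the W81A strain against the deletion strain (adjusted p = 0.0475). Counts of members by list are given after adjustment over all genes and after adjustment over the list alone.

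Genes named in the text came from a rule set before the data were examined. It took TAF14 and the marker genes in every group. It took the 8 largest rises and 8 largest falls of each comparison that were called, had a mean log2 CPM of at least 3 over the 12 libraries, had non-overlapping groups and had a standard gene name. It also took the 4 members with the smallest p from each list. The haploid-specific genes and the retrotransposon genes were chosen after values were seen.

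The alternatives tried were DESeq2 1.42.0, limma-voom, relative log expression and upper-quartile scaling, no filter, a filter of 10 CPM in 3 libraries, a robust dispersion fit, protein-coding nuclear genes alone, a fit of each comparison's 6 libraries alone, leaving out each library in turn, leaving out chromosome XII, a replicate term, a 2-fold limit and an estimated correlation. The pipeline was tested on simulated data with known changes before it was run. W81A and deletion effects were compared by the direct test of the W81A strain against the deletion strain. Overlap and correlation between comparisons were computed only for pairs that share no libraries. Sequence reads, allele sequence and splice forms were not analysed here.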

Results

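With the acetyl-lysine pocket of Taf14 mutated, mating genes of these a cells were lower and histone and G1/S genes higher, as lists, than with plasmid-borne TAF14 and than in wild type. These calls had adjusted p = 0.31 with an estimated correlation against the TAF14 strain, and 0.383 to 0.445 against wild type. In the deletion strain, mating genes were lower, and heat shock, stress, proteasome and amino acid genes were higher, as lists, than in either. Here adjusted p = 0.153 to 0.316 with an estimated correlation against the TAF14 strain, and 0.202 to 0.301 against wild type. All 3 deletion libraries carried an upward shift of chromosome XII genes, absent from the wild type and W81A libraries. Effects of losing TAF14 and of that shift cannot be told apart in comparisons with the deletion strain. Heat shock chaperones, the proteasome and amino acid biosynthesis were lower in the W81A strain than in the deletion strain in a direct test (adjusted p = 0.0475, 0.202 and 0.202 with an estimated correlation), and so was the carbonic anhydrase gene NCE103. Taf14 is a subunit of TFIID, TFIIF, INO80, SWI/SNF, RSC and NuA3, and its YEATS domain binds acylated lysines of histone H3. All strains derive from haploid BY4741, of mating type a. Single-gene changes are log2 fold changes ± standard error, with n = 3 per group.

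TAF14 (YPL129W, chromosome XVI 305298-306137, plus strand, 2 exons, build R64) was read first in each library. Wild type libraries had 132, 129 and 148 CPM, the deletion strain 0.437, 0.199 and 0.484, the TAF14 strain 355, 143 and 302, and the W81A strain 223, 203 and 192. The TAF14 change was -9.43 ± 0.46 in the deletion strain against the TAF14 strain and -8.47 ± 0.48 against wild type (adjusted p = 7.61e-09 and 3.14e-08). The W81A change against the TAF14 strain, -0.37 ± 0.23, was not called with all libraries (adjusted p = 0.232). Against wild type, the TAF14 change was 0.96 ± 0.23 in the TAF14 strain (adjusted p = 0.0137) and 0.59 ± 0.23 in the W81A strain (adjusted p = 0.0737, not called). The first call was lost without replicate 1 of wild type or of the TAF14 strain (adjusted p = 0.052 and 0.0568).

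SPO19 (YPL130W, chromosome XVI 304387-305058, plus strand), the meiosis-specific neighbour upstream of TAF14, was high in both plasmid strains. No plasmid map was available, so a copy on the insert cannot be told apart from a response of the chromosomal gene, here or where SPO19 is named below. It had 0.889 ± 0.222 CPM in wild type and 2.94 ± 0.140 in the deletion strain, against 89.9 ± 43.5 in the TAF14 strain and 60.8 ± 3.33 in the W81A strain. TBF1 (YPL128C, chromosome XVI 306533-308221, minus strand), the neighbour on the other side, had 75.3, 70.6, 73.0 and 76.8 CPM in wild type, deletion, TAF14 and W81A strains. HIS3 (YOR202W, chromosome XV 721946-722608), the marker of the pRS313-type vector, had 297 ± 26.0 CPM in wild type, 629.9 ± 91.5 in the deletion strain, 932 ± 331 in the TAF14 strain and 652 ± 16.4 in the W81A strain. It rose in the TAF14 strain against wild type (1.65 ± 0.21, adjusted p = 0.000254). CYC8 (YBR112C, also named SSN6), the gene named in the vector's label, had 169.4 ± 5.98, 163.7 ± 28.0, 144.8 ± 10.6 and 147.7 ± 10.5 CPM in the same order. LEU2, URA3 and MET17, absent from BY4741, had 0 counts in all 12 libraries (at most 0.327 CPM).

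Replicate 2 of the TAF14 strain stood apart from replicates 1 and 3. It had 142.7 CPM of TAF14, 40.4 of SPO19 and 557 of HIS3. The other 2 averaged 328.5, 114.6 and 1119, and the W81A strain 205.9, 60.8 and 652. Less plasmid in the W81A strain than in those 2 is left open. The stress gene HSP12 had 164.5 CPM in replicate 2 and 6.18 in each of the other 2. Genes of chromosome XII were shifted upward as a set in this library, by 0.573 in log2 (95% interval 0.546 to 0.594), and in deletion replicates 1, 2 and 3, by 0.485 (0.440 to 0.525), 0.499 (0.464 to 0.535) and 0.537 (0.503 to 0.579). The other 8 libraries lay between -0.00473 and 0.0336. Of the named genes, SST2, GSY2, HSP104, NCW2, ACO1, SSA2, CPR6, ERG3, TPO1, AHP1 and COX8 lie on chromosome XII. Principal component 1, with 48.8% of the variance, placed the deletion libraries at 26.6 to 28.6, the W81A libraries at 0.546 to 0.997, wild type at -12.2 to -11.2 and the TAF14 strain at -20.9 to -8.65. Component 2, with 19.1%, placed the W81A libraries at 18.6 to 19.2 and all others at -7.79 to -5.66.

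**Figure D1:**
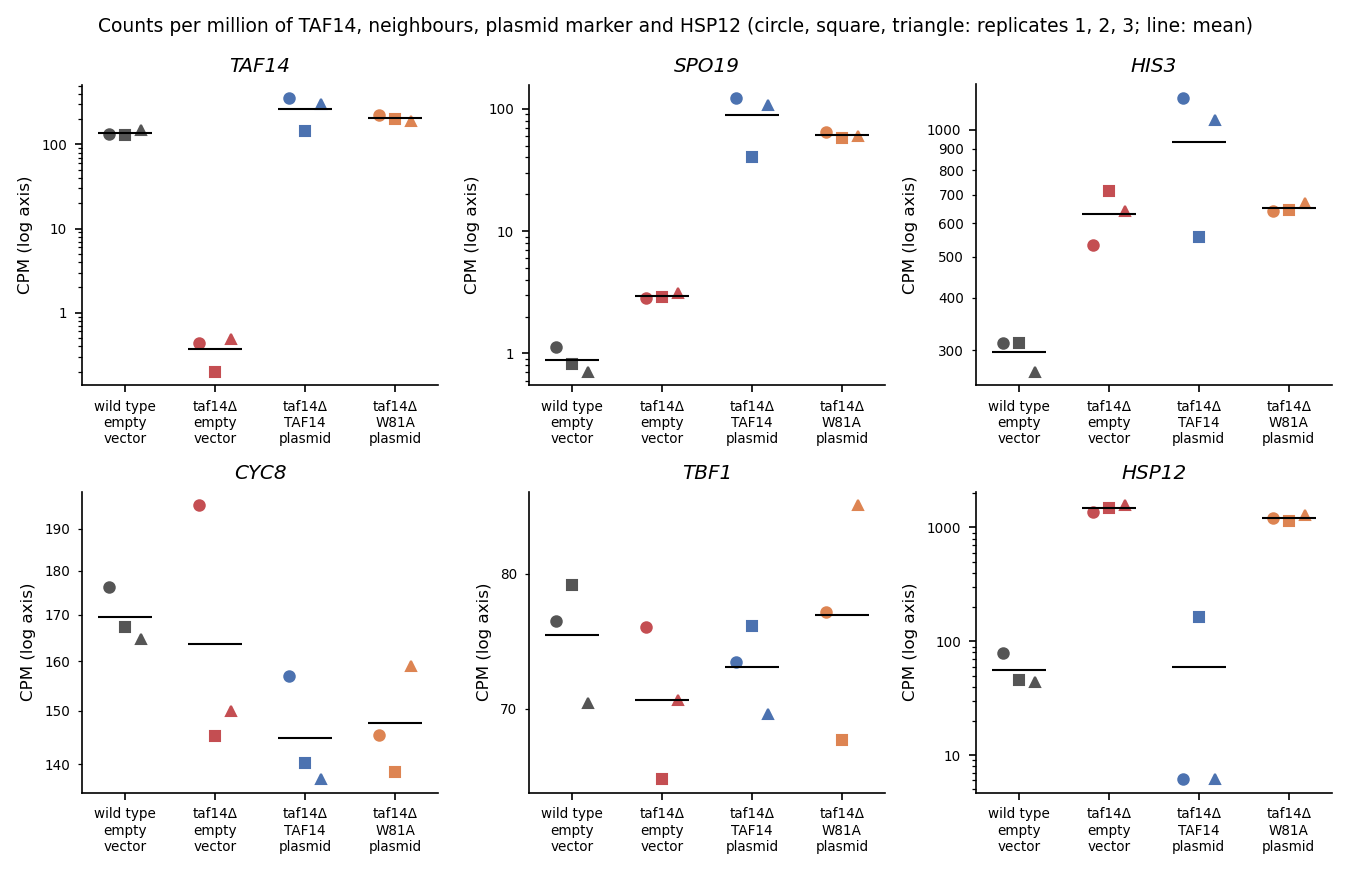
CPM of TAF14, its neighbours SPO19 and TBF1, the vector genes HIS3 and CYC8, and HSP12 in each of the 12 libraries. TAF14 averaged 0.373 CPM in the deletion strain and SPO19 averaged 89.9 CPM in the TAF14 strain.

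In the W81A strain against the TAF14 strain, most pheromone-response genes fell and HSP12, CHA1 and GAP1 rose. BAR1 (YIL015W, chromosome IX 322342-324105), the protease that degrades alpha-factor, was 9.33-fold lower (41.6 ± 3.09 against 388 ± 118 CPM, -3.22 ± 0.18, adjusted p = 1.98e-07). MFA1 (YDR461W, chromosome IV 1385176-1385286), which encodes an a-factor precursor, was 6.32-fold lower (14.7 ± 0.459 against 92.9 ± 24.0 CPM, -2.66 ± 0.18). CHA1 (YCL064C, chromosome III 15798-16880), the serine and threonine deaminase, was 9.62-fold higher (199.8 ± 8.66 against 20.3 ± 17 CPM, 3.27 ± 0.37, adjusted p = 3.09e-05). HSP12 (YFL014W, chromosome VI 107256-107585), a small membrane-protecting stress protein, was 20.4-fold higher (4.35 ± 0.87, adjusted p = 0.00222). Its 3 W81A libraries had 1151 to 1299 CPM. Without replicate 2 of the TAF14 strain the HSP12 change was 7.62 and the CHA1 change 4.25.

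GAP1 (YKR039W, chromosome XI 515063-516871), the general amino acid permease, rose by 2.22 ± 0.16 (39.8 ± 4.25 against 8.49 ± 1.62 CPM). ARG3 (YJL088W, chromosome X 268799-269815), ornithine carbamoyltransferase, rose by 2.21 ± 0.10 (180.4 ± 18.2 against 39.1 ± 6.11 CPM, adjusted p = 3.94e-08). HOR7, a hyperosmolarity-responsive gene, rose by 2.45 ± 0.34, and by 3.32 without replicate 2 of the TAF14 strain. MSC1 (YML128C, chromosome XIII 15135-16676) rose by 2.08 ± 0.15, the glycerol-phosphatase gene GPP2 by 1.91 ± 0.13 and the sterol-binding protein gene PRY1 by 1.79 ± 0.19. Among the largest falls, PRM7 (YDL039C, chromosome IV 381985-384081), a pheromone-regulated membrane protein gene, fell (-2.92 ± 0.39, 52.4 ± 5.17 against 398 ± 244 CPM), and wild type had 53.4 ± 11.8 CPM. BSC1 fell (-2.57 ± 0.41, 14.3 ± 2.71 against 85.2 ± 51.3 CPM), and wild type had 15.0 ± 3.93 CPM. For both genes the TAF14 strain, and not the W81A strain, departed from wild type. NDJ1, a meiotic telomere protein gene, fell (-2.53 ± 0.33).

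Of the 21 pheromone-response and a-specific genes, 17 fell, 0 rose and 4 were not called, or 17 and 1 when adjusted over the list alone (median -0.94, adjusted p = 3.38e-10, and adjusted p = 0.31 with an estimated correlation). FUS1 (YCL027W, chromosome III 71803-73341), needed for cell fusion, fell (-2.89 ± 0.45, 4.39 ± 1.12 against 33.1 ± 19.1 CPM). SST2 (YLR452C, chromosome XII 1039270-1041366), the regulator that desensitizes cells to pheromone, fell (-2.50 ± 0.11), and AGA2 (YGL032C, chromosome VII 436570-436833), a subunit of a-agglutinin, (-2.08 ± 0.26). FAR1 (YJL157C, chromosome X 123836-126328), which arrests the cell cycle in response to pheromone, fell (-1.73 ± 0.10). None of the 4 tested alpha-specific genes was called here, but in each other comparison 1 or 2 fell or 1 rose.

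Cell-cycle lists moved in different directions. All 11 tested histone genes rose, also when adjusted over the list alone (median 0.60, adjusted p = 4.8e-07, and adjusted p = 0.31 with an estimated correlation). HTB2 (YBL002W, chromosome II 236492-236887), for histone H2B, rose by 0.77 ± 0.06 and HHT2, for H3, by 0.75 ± 0.08. Of 24 G1/S genes, 17 rose, 2 fell and 5 were not called, or 17 and 2 when adjusted over the list alone (median 0.35, adjusted p = 1.7e-05, and adjusted p = 0.31 with an estimated correlation). TOS6 rose by 1.38 ± 0.15, the G1 cyclin gene PCL1 by 0.78 ± 0.10, the thymidylate synthase gene CDC21 by 0.63 ± 0.07 and the cohesin subunit gene MCD1 by 0.55 ± 0.06. Of 14 G2/M genes, 12 fell, 1 rose and 1 was not called, or 12 and 1 when adjusted over the list alone (median -0.48, adjusted p = 7.63e-06, and adjusted p = 0.31 with an estimated correlation). CDC20 (YGL116W, chromosome VII 289809-291641), the activator of the anaphase-promoting complex, fell (-0.90 ± 0.07) and the polo kinase gene CDC5 (-0.64 ± 0.07). The M/G1 list was not called (5 higher and 3 lower of 14, or 5 and 4 when adjusted over the list alone, median -0.0396, adjusted p = 0.936), and its mean of 0.00734 had the opposite sign to its median.

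The DNA damage response list was not called as a list (5 higher and 7 lower of 20, or 5 and 7 when adjusted over the list alone, median -0.0286, adjusted p = 0.705, and adjusted p = 0.742 with an estimated correlation). RNR1 (YER070W, chromosome V 298950-301616), the large ribonucleotide reductase subunit, rose by 0.93 ± 0.07 (adjusted p = 1.54e-06) and the checkpoint kinase gene DUN1 by 0.39 ± 0.08. RAD16, of nucleotide excision repair, fell (-0.85 ± 0.08) and the DNA glycosylase gene MAG1 was lower (7.73 ± 1.76 against 15.5 ± 4.36 CPM).

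Of 134 cytosolic ribosomal protein genes, 90 fell, 1 rose and 43 were not called, or 105 and 2 when adjusted over the list alone (median -0.30, adjusted p = 1.61e-15, and adjusted p = 0.468 with an estimated correlation). RPL17B fell (-0.45 ± 0.06) and RPL17A (-0.36 ± 0.06). RPL7B, at -0.80 ± 0.07, matched another gene over 40.9% of its length and its value is uncertain. Of 53 ribosome biogenesis genes, 14 fell, 1 rose and 38 were not called, or 13 and 1 when adjusted over the list alone (median -0.12, adjusted p = 0.00136, and adjusted p = 0.448 with an estimated correlation). The nucleolar protein gene NSR1 fell (-0.37 ± 0.06) and MAK16 (-0.26 ± 0.05). Of 19 RNA polymerase I and III subunit genes, 9 fell, 0 rose and 10 were not called, or 9 and 0 when adjusted over the list alone (median -0.17, adjusted p = 0.00235, and adjusted p = 0.31 with an estimated correlation). RPC53 was among them, at -0.30 ± 0.06. Against wild type the W81A strain had 7 biogenesis genes up and 1 down (median 0.0615, adjusted p = 0.0622) and 1 polymerase gene up and 1 down (median 0.00176, adjusted p = 0.985).

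Of 32 proteasome genes, 15 fell, 0 rose and 17 were not called, or 17 and 0 when adjusted over the list alone (median -0.18, adjusted p = 1.7e-05, and adjusted p = 0.468 with an estimated correlation). RPN12 (YFR052W, chromosome VI 252505-253329) fell (-0.35 ± 0.06) and PRE7 (-0.32 ± 0.05). Against wild type 2 proteasome genes were up and 1 down in the W81A strain (median -0.0501), and the TAF14 strain had a median of 0.14. Of 25 heat shock chaperone genes, 14 fell, 2 rose and 9 were not called, or 15 and 2 when adjusted over the list alone (median -0.38, adjusted p = 0.0016, and adjusted p = 0.348 with an estimated correlation). The Hsp90 cochaperone gene STI1 (YOR027W, chromosome XV 381053-382822) fell (-0.70 ± 0.08), as did the Hsp40 gene YDJ1 (YNL064C, chromosome XIV 505868-507097, -0.63 ± 0.06) and CPR6 (-0.57 ± 0.07). SSA2, on chromosome XII, read -0.86 ± 0.07 but shares 100% of its length with a near copy. Chromosome XII genes as a set were shifted by -0.221 in this comparison and by -0.00366 without replicate 2 of the TAF14 strain.

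Of 32 respiratory-chain and ATP synthase genes, 18 rose, 0 fell and 14 were not called, or 18 and 1 when adjusted over the list alone (median 0.36, adjusted p = 4.8e-07, and adjusted p = 0.468 with an estimated correlation). Against wild type 4 of these genes were higher and 4 lower in the W81A strain (median -0.0905, adjusted p = 0.468), and in the TAF14 strain the list median was -0.41. The ATP synthase genes ATP18 and ATP16 rose by 0.68 ± 0.07 and 0.65 ± 0.07. Of 15 tricarboxylic acid cycle genes, 5 rose, 1 fell and 9 were not called, or 5 and 1 when adjusted over the list alone (median 0.29, adjusted p = 0.0307, and adjusted p = 0.57 with an estimated correlation). KGD2 rose by 0.42 ± 0.07 and CIT1 fell (-0.49 ± 0.09). This call was lost without replicate 1 or 3 of the TAF14 strain (adjusted p = 0.0651 and 0.0979). The mitochondrially encoded list was not called (0 higher and 0 lower of 6, or 0 and 0 when adjusted over the list alone, median 0.19, adjusted p = 0.391).

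More amino acid genes rose than fell against the TAF14 strain, and the reverse held against wild type. Of 39 in the list, 17 rose, 9 fell and 13 were not called, or 18 and 10 when adjusted over the list alone (median 0.15, adjusted p = 0.0226, and adjusted p = 0.57 with an estimated correlation). The call was lost without W81A replicate 3 (adjusted p = 0.0549). In the W81A strain against wild type 9 were higher and 16 lower (median -0.13, adjusted p = 0.109), and in the TAF14 strain against wild type 1 was higher and 17 lower. The arginine genes ARG56 and ARG8 rose by 1.41 ± 0.09 and 0.98 ± 0.08, and the branched-chain transaminase gene BAT1 fell (-0.96 ± 0.07). Of 19 nitrogen catabolite repression genes, 6 rose, 1 fell and 12 were not called, or 6 and 1 when adjusted over the list alone (median 0.30, adjusted p = 0.0307, and adjusted p = 0.57 with an estimated correlation). The permease gene AGP1 rose by 1.17 ± 0.10, and the list call was lost without W81A replicate 2 (adjusted p = 0.0549). Of 14 purine and one-carbon genes, 8 fell, 2 rose and 4 were not called, or 9 and 3 when adjusted over the list alone (median -0.29, adjusted p = 0.0101, and adjusted p = 0.57 with an estimated correlation). MTD1 fell (-0.79 ± 0.06), and the list call was lost without replicate 2 of the TAF14 strain (adjusted p = 0.0823). Of 23 sulfur and methionine genes, 9 fell, 1 rose and 13 were not called, or 9 and 1 when adjusted over the list alone (median -0.16, adjusted p = 0.04, and adjusted p = 0.57 with an estimated correlation). The methionine permease gene MUP3 fell (-1.51 ± 0.19). Without replicate 1 or 3 of the TAF14 strain the sulfur list had adjusted p = 0.098 and 0.0853, without chromosome XII 0.101, and with no filter on low counts 0.058.

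Of 29 general stress genes, 12 rose, 3 fell and 14 were not called, or 12 and 3 when adjusted over the list alone (median 0.26, adjusted p = 0.0307, and adjusted p = 0.57 with an estimated correlation). Without replicate 1 or 3 of the TAF14 strain this call was lost (adjusted p = 0.0627 and 0.0853). DDR2, a multistress gene, rose by 2.58 ± 0.28, the glucokinase gene GLK1 (YCL040W, chromosome III 50838-52340) rose by 1.27 ± 0.19, uncertain for its overlap with YCL042W, and the glycogen-branching enzyme gene GLC3 fell (-1.12 ± 0.10). Of 125 tested genes within 20 kb of a chromosome end, 35 fell, 8 rose and 82 were not called, or 36 and 8 when adjusted over the list alone (median -0.24, adjusted p = 0.00226, and adjusted p = 0.31 with an estimated correlation).

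The iron regulon had 9 higher and 3 lower of 22, or 9 and 3 when adjusted over the list alone, median 0.14, adjusted p = 0.0734. Its high-affinity iron uptake genes FTR1 and FET3 rose by 1.52 ± 0.11 and 1.37 ± 0.09, and the enterobactin transporter gene ENB1 fell (-1.43 ± 0.18). Ergosterol synthesis had 5 higher and 9 lower of 26, or 5 and 11 when adjusted over the list alone, median -0.15, adjusted p = 0.247. ERG25 was up by 1.09 ± 0.06, ERG3 was up by 0.78 ± 0.07 and ERG28 was down (-0.82 ± 0.10). The PHO regulon had 0 higher and 5 lower of 16, or 0 and 5 when adjusted over the list alone, median -0.23, adjusted p = 0.0579. The repressible acid phosphatase gene PHO5 was down (-0.88 ± 0.20). PHO3 (YBR092C, chromosome II 427698-429101), the thiamine-repressible acid phosphatase, fell (-2.03 ± 0.07, adjusted p = 1.03e-09). The thiamine list had 0 higher and 2 lower of 9, or 0 and 2 when adjusted over the list alone, median -0.0476, adjusted p = 0.391. Cell wall integrity had 2 higher and 5 lower of 13, or 2 and 7 when adjusted over the list alone, median -0.40, adjusted p = 0.247. The kinase gene SLT2 was down (-0.75 ± 0.07) and its target PRM5 (-0.99 ± 0.10).

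TFIID and TFIIF subunits had 2 higher and 2 lower of 15, or 2 and 2 when adjusted over the list alone, median 0.0592, adjusted p = 0.788, and the mean of their changes was -0.00843. INO80, SWI/SNF, RSC and NuA3 subunits had 8 higher and 1 lower of 40, or 6 and 1 when adjusted over the list alone, median 0.11, adjusted p = 0.0595. The NuA3 acetyltransferase gene SAS3 was down (-0.48 ± 0.08) and SNF12 up by 0.35 ± 0.07. Inositol and phospholipid synthesis had 4 higher and 1 lower of 16, or 6 and 2 when adjusted over the list alone, median 0.11, adjusted p = 0.333. Gluconeogenesis, glyoxylate and acetate use had 3 higher and 0 lower of 17, or 1 and 0 when adjusted over the list alone, median 0.20, adjusted p = 0.391. Meiosis and sporulation had 1 higher and 4 lower of 20, or 1 and 1 when adjusted over the list alone, median -0.14, adjusted p = 0.274. The unfolded protein response had 0 higher and 1 lower of 10, or 0 and 0 when adjusted over the list alone, median -0.10, adjusted p = 0.314. Oxidative stress had 4 higher and 4 lower of 15, or 5 and 5 when adjusted over the list alone, median -0.0771, adjusted p = 0.935. For that list camera pointed upward, while its mean of -0.0580 and its median were below 0.

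Glycolysis and fermentation had 2 higher and 1 lower of 17, or 1 and 1 when adjusted over the list alone, median 0.0628, adjusted p = 0.57. The hexokinase gene HXK2 was down (-0.84 ± 0.09). Hexose transport had 1 higher and 2 lower of 12, or 1 and 2 when adjusted over the list alone, median -0.15, adjusted p = 0.274. HXT4 was down (-1.26 ± 0.18). Galactose use had 0 higher and 2 lower of 6, or 0 and 2 when adjusted over the list alone, median -0.15, adjusted p = 0.57. Flocculins had 0 higher and 2 lower of 5, or 0 and 2 when adjusted over the list alone, median -0.21, adjusted p = 0.148. Drug efflux had 1 higher and 1 lower of 8, or 1 and 1 when adjusted over the list alone, median 0.17, adjusted p = 0.428.

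There were 1954 calls, 938 up and 1016 down, and 2716 genes with non-overlapping groups, with 10% by chance. Of the 471 tested genes of chromosome XII, 8 were up and 127 down. Without replicate 2 of the TAF14 strain they were 88 and 96, out of 2149 calls in total.

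**Figure D2:**
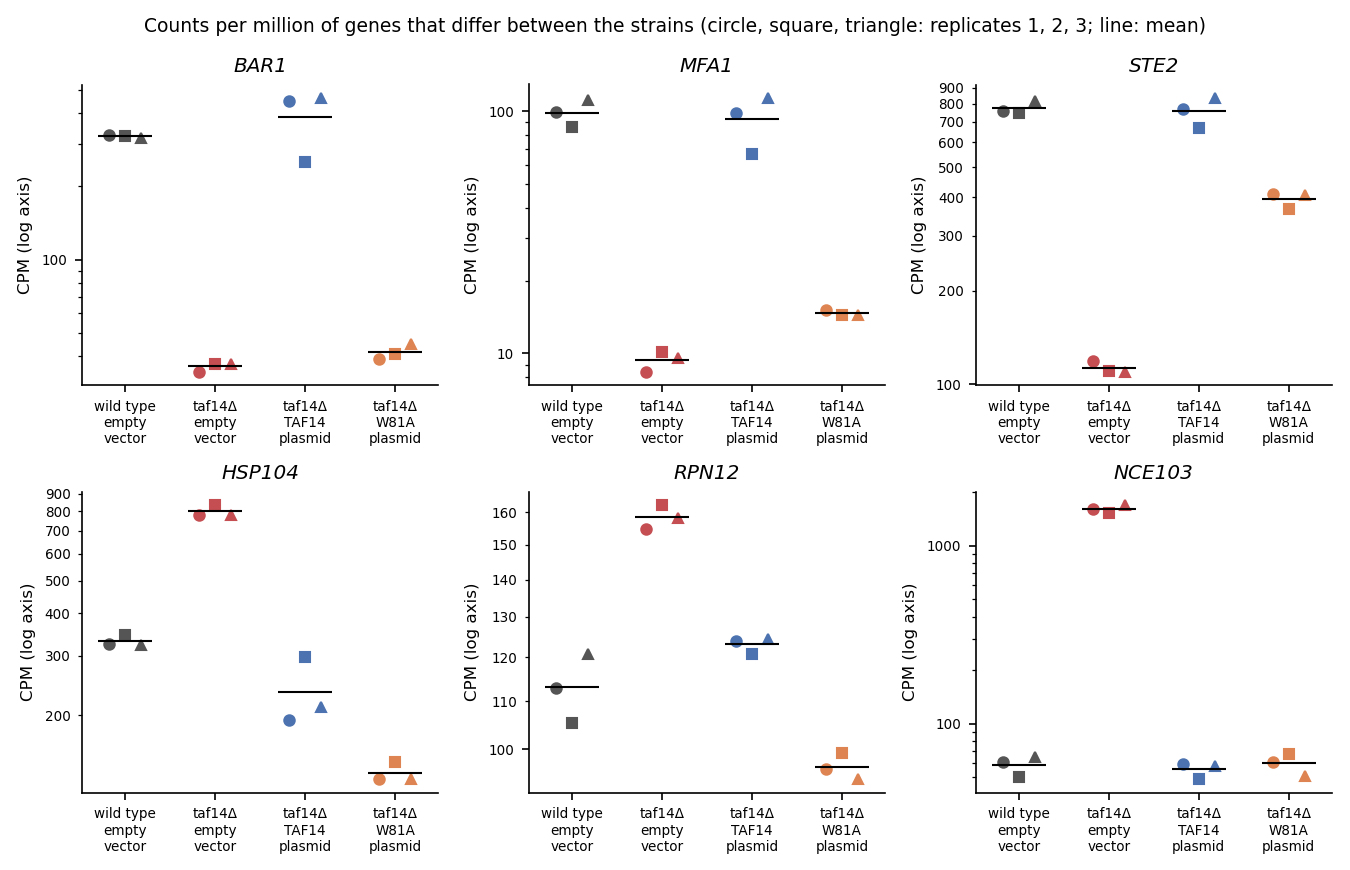
CPM of BAR1, MFA1, STE2, HSP104, RPN12 and NCE103 in each library, with a line at each group's mean. BAR1 averaged 41.6 CPM in the W81A strain and 36.3 in the deletion strain.

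In the deletion strain against the TAF14 strain, NCE103, SNZ1 and most stress genes rose and most mating genes fell. NCE103 (YNL036W, chromosome XIV 559814-560479), carbonic anhydrase, was 29.2-fold higher (1614 ± 77.3 against 55.4 ± 5.67 CPM, 4.87 ± 0.13, adjusted p = 6.32e-11). SNZ1 (YMR096W, chromosome XIII 458408-459301), of vitamin B6 synthesis, was 12.5-fold higher (402 ± 31.1 against 32.0 ± 4.93 CPM, 3.65 ± 0.12). COS10 (YNR075W, chromosome XIV 779916-781040), a subtelomeric gene of endosomal protein sorting, was lower (0.906 ± 0.227 against 17.6 ± 4.29 CPM, -4.24 ± 0.27). HSP12 was 24.6-fold higher (4.62 ± 0.88), and its change was 7.90 without replicate 2 of the TAF14 strain. MSC1 rose by 3.63 ± 0.15, the hexokinase gene HXK1 (YFR053C, chromosome VI 253592-255049) by 2.99 ± 0.19 and GLK1 by 2.85 ± 0.19. The trehalose synthase subunit gene TSL1 rose by 2.76 ± 0.17 and the mitochondrial reductase gene MCR1 by 2.74 ± 0.10.

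Among the falls, SPO19 was at -4.92 ± 0.39, NDJ1 at -3.83 ± 0.38 and RDS1 (YCR106W, chromosome III 310958-313456), a zinc-cluster gene, at -3.48 ± 0.50. AAD3, next to RDS1, was at -3.62 ± 0.61, with a near copy over 39.6% of its length. BAR1 fell (-3.42 ± 0.19, 36.3 ± 1.55 against 388 ± 118 CPM) and PRM7 (-3.41 ± 0.41). Of 21 pheromone-response genes, 18 fell, 0 rose and 3 were not called, or 18 and 0 when adjusted over the list alone (median -1.52, adjusted p = 2.45e-10, and adjusted p = 0.199 with an estimated correlation). STE2 (YFL026W, chromosome VI 82580-83875), the alpha-factor receptor, fell (-2.74 ± 0.09, 113 ± 5.15 against 757 ± 82.9 CPM), FAR1 (-2.43 ± 0.10) and SST2 (-2.39 ± 0.11). Of 4 alpha-specific genes 1 fell and 0 rose (median -0.38).

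Of 29 general stress genes, 23 rose, 1 fell and 5 were not called, or 24 and 1 when adjusted over the list alone (median 1.71, adjusted p = 4.84e-10, and adjusted p = 0.153 with an estimated correlation). The catalase gene CTT1 rose by 2.60 ± 0.14 and OM45 by 2.08 ± 0.10. Of 25 heat shock chaperone genes, 21 rose, 1 fell and 3 were not called, or 22 and 1 when adjusted over the list alone (median 0.83, adjusted p = 1.21e-09, and adjusted p = 0.153 with an estimated correlation). The Hsp90 cochaperone gene AHA1 (YDR214W, chromosome IV 892875-893927) rose by 1.07 ± 0.06 and HSP42 by 1.90 ± 0.12. Of 39 amino acid genes, 32 rose, 2 fell and 5 were not called, or 32 and 2 when adjusted over the list alone (median 0.78, adjusted p = 1.89e-13, and adjusted p = 0.153 with an estimated correlation). HIS5 (YIL116W, chromosome IX 142928-144085), of histidine synthesis, rose by 2.06 ± 0.06. Of 32 proteasome genes, 22 rose, 0 fell and 10 were not called, or 23 and 0 when adjusted over the list alone (median 0.25, adjusted p = 1.13e-05, and adjusted p = 0.316 with an estimated correlation). RPT4 rose by 0.62 ± 0.06.

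Of 134 ribosomal protein genes, 106 fell, 0 rose and 28 were not called, or 109 and 1 when adjusted over the list alone (median -0.39, adjusted p = 1.67e-15, and adjusted p = 0.343 with an estimated correlation). Of 53 ribosome biogenesis genes, 37 fell, 0 rose and 16 were not called, or 38 and 0 when adjusted over the list alone (median -0.29, adjusted p = 5.74e-10, and adjusted p = 0.153 with an estimated correlation). NSR1 fell (-1.03 ± 0.06). Of 19 RNA polymerase I and III genes, 13 fell, 0 rose and 6 were not called, or 13 and 0 when adjusted over the list alone (median -0.26, adjusted p = 5.65e-05, and adjusted p = 0.153 with an estimated correlation). RPA135 fell (-0.50 ± 0.06). Of 32 respiratory-chain and ATP synthase genes, 27 rose, 1 fell and 4 were not called, or 29 and 1 when adjusted over the list alone (median 0.54, adjusted p = 2.03e-09, and adjusted p = 0.279 with an estimated correlation). The complex III gene COR1 rose by 0.96 ± 0.09. All 15 tricarboxylic acid cycle genes rose, also over the list alone (median 0.65, adjusted p = 2.42e-06, and adjusted p = 0.279 with an estimated correlation). LSC2 rose by 1.18 ± 0.15. All 6 tested mitochondrially encoded genes rose, also over the list alone (median 0.98, adjusted p = 0.00622, and adjusted p = 0.429 with an estimated correlation). COX2 rose by 1.11 ± 0.20. Mitochondrial genes held 0.841% to 1.03% of counts in deletion libraries and 0.444% to 0.760% in the others.

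All 14 G2/M genes fell, also over the list alone (median -0.62, adjusted p = 3.45e-07, and adjusted p = 0.197 with an estimated correlation). The mitotic cyclin gene CLB2 fell (-1.15 ± 0.08) and HOF1 (-1.17 ± 0.08). Of 14 M/G1 daughter-cell genes, 13 rose, 1 fell and 0 were not called, or 13 and 1 when adjusted over the list alone (median 0.98, adjusted p = 4.31e-06, and adjusted p = 0.25 with an estimated correlation). The cell-separation gene DSE4 rose by 1.57 ± 0.07. Histones were not called as a list (5 higher and 2 lower of 11, or 5 and 2 when adjusted over the list alone, median 0.0768, adjusted p = 0.207). HTB2 rose by 0.78 ± 0.06. The DNA damage list was not called either (3 higher and 4 lower of 20, or 3 and 4 when adjusted over the list alone, median -0.20, adjusted p = 0.563). RNR2 fell (-0.85 ± 0.06). The G1/S list was not called (6 higher and 5 lower of 24, or 6 and 5 when adjusted over the list alone, median 0.0121, adjusted p = 0.878), and its mean was -0.00200, opposite in sign to its median.

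Of 125 chromosome-end genes, 54 fell, 17 rose and 54 were not called, or 56 and 17 when adjusted over the list alone (median -0.37, adjusted p = 0.000607, and adjusted p = 0.197 with an estimated correlation). Of 16 inositol and phospholipid genes, 10 fell, 1 rose and 5 were not called, or 10 and 1 when adjusted over the list alone (median -0.28, adjusted p = 0.0232, and adjusted p = 0.429 with an estimated correlation). CHO2 fell (-0.86 ± 0.09). Without replicate 2 of the TAF14 strain that list had adjusted p = 0.124. Meiosis genes had 7 members down, 1 up and 12 not called, or 7 and 1 when adjusted over the list alone (median -0.31, adjusted p = 0.0368, and adjusted p = 0.311 with an estimated correlation). That call was lost without deletion replicate 1, replicate 1 of the TAF14 strain or chromosome XII genes (adjusted p = 0.0691, 0.0511 and 0.056). Nitrogen catabolite repression genes had 10 members up, 3 down and 6 not called, or 10 and 3 when adjusted over the list alone (median 0.43, adjusted p = 0.0396, and adjusted p = 0.471 with an estimated correlation). AGP1 rose by 1.90 ± 0.10, and the list call was lost without deletion replicate 2 or 3 and with a replicate term (adjusted p = 0.0709, 0.0743 and 0.0625). There were 2893 calls, 1428 up and 1465 down, and 3202 genes with non-overlapping groups, with 10% by chance. Of chromosome XII genes, shifted by 0.278 as a set, 176 were up and 37 down, and without replicate 2 of the TAF14 strain 344 were up and 31 down.

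In the deletion strain against wild type, NCE103, HSP12 and the iron gene FIT2 rose and COS10 and MFA1 fell. NCE103 was 27.4-fold higher (1614 ± 77.3 against 58.8 ± 7.49 CPM, 4.78 ± 0.13). FIT2 (YOR382W, chromosome XV 1059531-1059992), a cell-wall mannoprotein that retains siderophore iron, was 11.3-fold higher (137 ± 13.6 against 12.1 ± 0.155 CPM, 3.50 ± 0.24). MFA1 was 10.5-fold lower (9.38 ± 0.893 against 98.9 ± 12.8 CPM, -3.39 ± 0.19) and BAR1 8.88-fold lower (36.3 ± 1.55 against 322 ± 5.23 CPM, -3.15 ± 0.19). HSP12 rose by 4.72 ± 0.88, HXK1 by 3.25 ± 0.19, and MSC1 by 3.07 ± 0.14. The pyruvate carboxylase gene PYC1 rose by 2.68 ± 0.13, MCR1 by 2.55 ± 0.10 and GLK1 by 2.49 ± 0.19. COS10 fell (-3.89 ± 0.28), PHO5 (YBR093C, chromosome II 429548-430951, -3.05 ± 0.19), NDJ1 (-2.97 ± 0.41) and the membrane stress gene HSP30 (-2.97 ± 0.24). The phosphate transporter gene PHO84 (YML123C, chromosome XIII 24037-25800) read -3.43 ± 0.16, uncertain because another gene matches 100% of it.

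Of 32 proteasome genes, 31 rose, 0 fell and 1 was not called, or 31 and 0 when adjusted over the list alone (median 0.37, adjusted p = 2.88e-10, and adjusted p = 0.301 with an estimated correlation). RPT4 rose by 0.77 ± 0.06 and PRE7 by 0.76 ± 0.05. Of 25 chaperone genes, 21 rose, 1 fell and 3 were not called, or 21 and 1 when adjusted over the list alone (median 0.66, adjusted p = 4.42e-09, and adjusted p = 0.202 with an estimated correlation). AHA1 rose by 1.30 ± 0.06 and CPR6 by 1.28 ± 0.07. Of 29 stress genes, 22 rose, 3 fell and 4 were not called, or 22 and 3 when adjusted over the list alone (median 1.44, adjusted p = 9.5e-08, and adjusted p = 0.301 with an estimated correlation). CTT1 rose by 2.23 ± 0.13 and PGM2 by 1.68 ± 0.08. Of 39 amino acid genes, 27 rose, 1 fell and 11 were not called, or 28 and 2 when adjusted over the list alone (median 0.51, adjusted p = 1.64e-09, and adjusted p = 0.301 with an estimated correlation). HIS4 rose by 1.55 ± 0.08. Of 15 tricarboxylic acid cycle genes, 14 rose, 0 fell and 1 was not called, or 15 and 0 when adjusted over the list alone (median 0.48, adjusted p = 3.69e-06, and adjusted p = 0.343 with an estimated correlation). The aconitase gene ACO1 rose by 2.35 ± 0.15 and IDH2 by 1.72 ± 0.17. All 6 mitochondrially encoded genes rose (median 0.77, adjusted p = 0.0126, and adjusted p = 0.544 with an estimated correlation). The nuclear respiratory list was not called (10 higher and 3 lower of 32, or 10 and 3 when adjusted over the list alone, median 0.17, adjusted p = 0.0555). Of 14 M/G1 genes, 10 rose, 3 fell and 1 was not called, or 10 and 3 when adjusted over the list alone (median 0.55, adjusted p = 0.0113, and adjusted p = 0.544 with an estimated correlation). DSE4 rose by 1.10 ± 0.07.

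Of 21 pheromone-response genes, 16 fell, 0 rose and 5 were not called, or 16 and 0 when adjusted over the list alone (median -1.23, adjusted p = 5.13e-09, and adjusted p = 0.301 with an estimated correlation). STE2 fell (-2.78 ± 0.09) and FAR1 (-2.12 ± 0.10). Of 4 alpha-specific genes 2 fell and 0 rose (median -1.05). Of 16 PHO genes, 11 fell, 2 rose and 3 were not called, or 11 and 2 when adjusted over the list alone (median -1.27, adjusted p = 0.000901, and adjusted p = 0.343 with an estimated correlation). The polyphosphate gene VTC3 fell (-1.60 ± 0.10). Of 16 inositol and phospholipid genes, 11 fell, 1 rose and 4 were not called, or 12 and 1 when adjusted over the list alone (median -0.38, adjusted p = 0.00221, and adjusted p = 0.343 with an estimated correlation). The inositol-phosphate synthase gene INO1 (YJL153C, chromosome X 134332-135933) fell (-2.05 ± 0.25) and PSD1 (-1.01 ± 0.06). Of 134 ribosomal protein genes, 76 fell, 4 rose and 54 were not called, or 79 and 4 when adjusted over the list alone (median -0.26, adjusted p = 1.32e-07, and adjusted p = 0.596 with an estimated correlation). Of 53 biogenesis genes, 25 fell, 4 rose and 24 were not called, or 26 and 4 when adjusted over the list alone (median -0.15, adjusted p = 0.00209, and adjusted p = 0.343 with an estimated correlation). Of 14 G2/M genes, 13 fell, 0 rose and 1 was not called, or 13 and 0 when adjusted over the list alone (median -0.54, adjusted p = 6.65e-06, and adjusted p = 0.301 with an estimated correlation). CDC5 fell (-0.71 ± 0.07). The G1/S list was not called (4 higher and 9 lower of 24, or 5 and 9 when adjusted over the list alone, median -0.15, adjusted p = 0.148). Chromosome-end genes had 47 members down, 21 up and 57 not called, or 48 and 21 when adjusted over the list alone (median -0.27, adjusted p = 0.0108, and adjusted p = 0.343 with an estimated correlation).

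DNA damage genes were not called as a list (2 higher and 3 lower of 20, or 1 and 3 when adjusted over the list alone, median 0.0488, adjusted p = 0.892). The small ribonucleotide reductase subunit gene RNR2 fell (-1.04 ± 0.06). Histones were not called as a list (3 higher and 4 lower of 11, or 3 and 4 when adjusted over the list alone, median -0.22, adjusted p = 0.892). HTB2 rose by 0.42 ± 0.06 and HTA1 fell (-0.95 ± 0.13). The peroxiredoxin gene AHP1, of the uncalled oxidative stress list (9 higher and 4 lower of 15, or 9 and 4 when adjusted over the list alone, median 0.43, adjusted p = 0.0841), rose by 2.15 ± 0.08. There were 2891 calls, 1420 up and 1471 down, and 3443 genes with non-overlapping groups, with 10% by chance. On chromosome XII, shifted by 0.508 as a set, 305 were up and 17 down, and 2569 calls lay elsewhere.

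**Figure D3:**
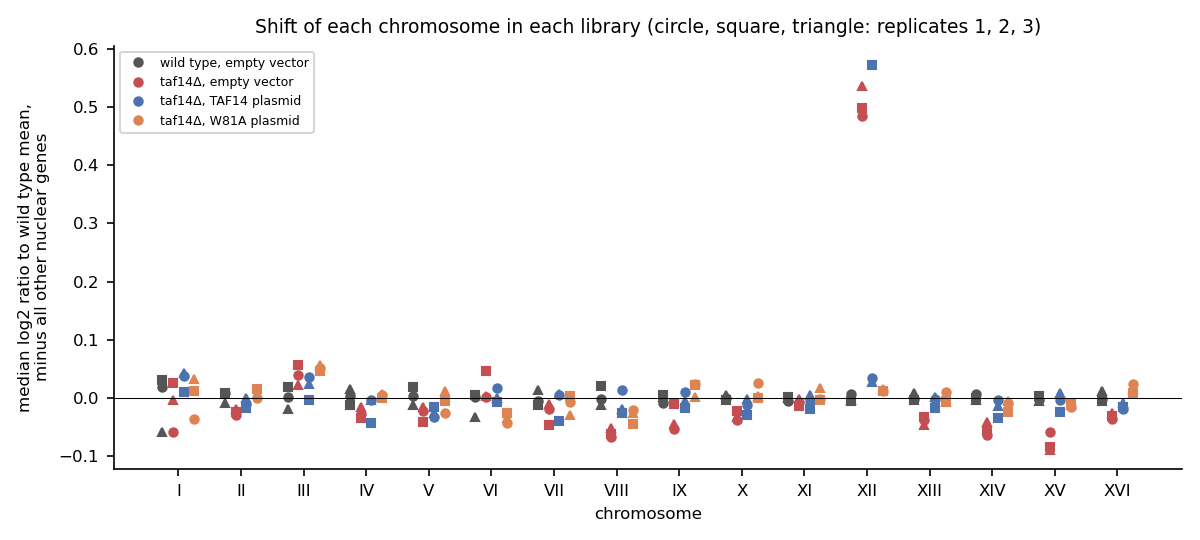
Median shift of each chromosome's genes in each library. Chromosome XII reached 0.573 in replicate 2 of the TAF14 strain and 0.485 to 0.537 in the deletion libraries.

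The W81A and deletion strains, which also differ in chromosome XII shift, were then compared directly. NCE103 was 26.9-fold lower in the W81A strain (60.0 ± 8.73 against 1614 ± 77.3 CPM, -4.75 ± 0.13). HSP104 (YLL026W, chromosome XII 88623-91349), the disaggregase, was 5.91-fold lower (135 ± 8.93 against 799 ± 29.0 CPM, -2.56 ± 0.13). OLE1 (YGL055W, chromosome VII 398628-400160), the fatty acid desaturase, was 4.03-fold higher (2088 ± 128 against 518 ± 14.8 CPM, 2.01 ± 0.11). STE2 was 3.49-fold higher (394 ± 23.2 against 113 ± 5.15 CPM), and COS10 9.76-fold higher (3.29 ± 0.29). TAF14 itself was at 9.06 ± 0.47 and SPO19 at 4.36 ± 0.40.

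RDS1 rose by 3.16 ± 0.51 and CHA1 was 3.99-fold higher. Lower genes were the glycogen synthase gene GSY2 on chromosome XII (-2.72 ± 0.34), TSL1 (-2.47 ± 0.17), SNZ1 (-2.42 ± 0.11), the cell wall gene NCW2 (-2.31 ± 0.30) and SER3, of serine synthesis (-2.30 ± 0.23). SER3 (YER081W, chromosome V 322686-324095) overlaps the noncoding gene SRG1, and its value is uncertain. Of 25 chaperone genes, 22 fell, 0 rose and 3 were not called, or 23 and 0 when adjusted over the list alone (median -1.13, adjusted p = 3.15e-14, and adjusted p = 0.0475 with an estimated correlation). AHA1 was 2.82-fold lower and CPR6 fell (-1.43 ± 0.07). Of 32 proteasome genes, 30 fell, 0 rose and 2 were not called, or 30 and 0 when adjusted over the list alone (median -0.40, adjusted p = 2.15e-12, and adjusted p = 0.202 with an estimated correlation). RPN12 fell (-0.71 ± 0.06). Of 39 amino acid genes, 30 fell, 0 rose and 9 were not called, or 30 and 0 when adjusted over the list alone (median -0.64, adjusted p = 3.68e-13, and adjusted p = 0.202 with an estimated correlation). HIS5 fell (-1.65 ± 0.06). Of 29 stress genes, 21 fell, 2 rose and 6 were not called, or 23 and 2 when adjusted over the list alone (median -1.13, adjusted p = 7.01e-09, and adjusted p = 0.202 with an estimated correlation). PGM2 fell (-1.60 ± 0.08) and YGP1 rose by 1.60 ± 0.09.

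Tricarboxylic acid cycle genes had 11 members down, 0 up and 4 not called, or 11 and 0 when adjusted over the list alone (median -0.53, adjusted p = 0.000486, and adjusted p = 0.524 with an estimated correlation). CIT1 fell (-1.08 ± 0.09). Respiratory-chain genes had 15 members down, 0 up and 17 not called, or 16 and 0 when adjusted over the list alone (median -0.18, adjusted p = 0.00585, and adjusted p = 0.635 with an estimated correlation), with COX8 at -1.07 ± 0.16. Mitochondrially encoded genes had 5 members down, 0 up and 1 not called, or 5 and 0 when adjusted over the list alone (median -0.68, adjusted p = 0.0132, and adjusted p = 0.548 with an estimated correlation). M/G1 genes had 13 members down, 1 up and 0 not called, or 13 and 1 when adjusted over the list alone (median -0.85, adjusted p = 1.76e-06, and adjusted p = 0.259 with an estimated correlation). DSE4 fell (-1.95 ± 0.08). Cell wall integrity genes had 8 members down, 1 up and 4 not called, or 9 and 1 when adjusted over the list alone (median -0.59, adjusted p = 0.00768, and adjusted p = 0.524 with an estimated correlation). PRM5 fell (-1.63 ± 0.10). Purine genes had 8 members down, 0 up and 6 not called, or 8 and 0 when adjusted over the list alone (median -0.25, adjusted p = 0.00623, and adjusted p = 0.524 with an estimated correlation). MTD1 fell (117 ± 6.39 against 234 ± 15.1 CPM).

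Pheromone-response genes had 7 members up, 0 down and 14 not called, or 7 and 0 when adjusted over the list alone (median 0.20, adjusted p = 0.00924, and adjusted p = 0.635 with an estimated correlation). FUS3 rose by 0.82 ± 0.10, MFA2 by 0.78 ± 0.09 and FAR1 by 0.71 ± 0.10. Ribosome biogenesis genes had 34 members up, 4 down and 15 not called, or 36 and 5 when adjusted over the list alone (median 0.21, adjusted p = 4.89e-06, and adjusted p = 0.206 with an estimated correlation). NSR1 rose by 0.66 ± 0.06. Ribosomal protein genes had 26 members up, 10 down and 98 not called, or 25 and 7 when adjusted over the list alone (median 0.13, adjusted p = 0.00623, and adjusted p = 0.803 with an estimated correlation). The call was lost without deletion replicate 1 or W81A replicate 3 (adjusted p = 0.123 and 0.0995). G1/S genes had 11 members up, 0 down and 13 not called, or 11 and 0 when adjusted over the list alone (median 0.22, adjusted p = 0.000486, and adjusted p = 0.202 with an estimated correlation). CLN1 rose by 1.46 ± 0.07. The DNA damage list was not called (4 higher and 6 lower of 20, or 4 and 7 when adjusted over the list alone, median 0.0564, adjusted p = 0.669), and RNR1 rose by 0.54 ± 0.07. Histones had 6 members up, 0 down and 5 not called, or 7 and 0 when adjusted over the list alone (median 0.36, adjusted p = 0.00623, and adjusted p = 0.524 with an estimated correlation). HTA1 rose by 1.09 ± 0.13. G2/M genes had 5 members up, 0 down and 9 not called, or 4 and 0 when adjusted over the list alone (median 0.16, adjusted p = 0.044, and adjusted p = 0.635 with an estimated correlation), and CLB1 was 2.83-fold higher. That call was lost without deletion replicate 2 or 3, or W81A replicate 1 or 3 (adjusted p = 0.0821, 0.0809, 0.0622 and 0.0565). Inositol and phospholipid genes had 12 members up, 2 down and 2 not called, or 13 and 2 when adjusted over the list alone (median 0.45, adjusted p = 0.00125, and adjusted p = 0.371 with an estimated correlation). INO1 rose by 1.76 ± 0.25. There were 2677 calls, 1343 up and 1334 down, and 3419 genes with non-overlapping groups, with 10% by chance. On chromosome XII, shifted by -0.475 as a set, 9 were up and 290 down, and 2378 calls lay elsewhere.

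In the W81A strain against wild type, HSP12 and the small heat shock gene HSP26 rose and BAR1, MFA1 and PHO5 fell. HSP26 (YBR072W, chromosome II 382030-382674) was 8.10-fold higher (47.8 ± 5.53 against 5.86 ± 1.99 CPM, 3.02 ± 0.25), and HSP12 rose by 4.44 ± 0.87. CHA1 rose by 2.84 ± 0.35, GAP1 by 2.22 ± 0.16, ARG3 by 1.90 ± 0.10, FIT2 by 1.89 ± 0.25, and ACO1 by 1.74 ± 0.15. SPO19, perhaps from the plasmid, rose by 6.07 ± 0.49. BAR1 fell (-2.96 ± 0.18), MFA1 (-2.75 ± 0.18), FUS1 (-2.26 ± 0.46) and SST2 (-2.13 ± 0.11). PHO5 fell (-2.89 ± 0.19), CIP1 (-2.53 ± 0.28) and the flavohemoglobin gene YHB1 (-2.14 ± 0.23). Pheromone-response genes had 13 members down, 0 up and 8 not called, or 15 and 0 when adjusted over the list alone (median -0.97, adjusted p = 5.11e-08, and adjusted p = 0.383 with an estimated correlation). FAR1 fell (-1.41 ± 0.10). Of 4 alpha-specific genes 0 rose and 1 fell, MF(ALPHA)1 (-4.18 ± 0.62, 1.47 CPM in wild type).

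PHO genes had 11 members down, 0 up and 5 not called, or 13 and 0 when adjusted over the list alone (median -1.21, adjusted p = 1.53e-07, and adjusted p = 0.383 with an estimated correlation). VTC3 fell (-1.30 ± 0.09). Glycolysis genes had 14 members up, 1 down and 2 not called, or 15 and 1 when adjusted over the list alone (median 0.59, adjusted p = 2.01e-07, and adjusted p = 0.383 with an estimated correlation). The aldolase gene FBA1 rose by 0.90 ± 0.10 and TPI1 by 0.71 ± 0.09. Drug efflux genes had 6 members up, 0 down and 2 not called, or 7 and 0 when adjusted over the list alone (median 0.46, adjusted p = 0.0035, and adjusted p = 0.321 with an estimated correlation). The transporter gene PDR5 rose by 1.45 ± 0.23. Histones had 7 members up, 0 down and 4 not called, or 8 and 0 when adjusted over the list alone (median 0.33, adjusted p = 0.000646, and adjusted p = 0.445 with an estimated correlation), with HTB2 at 0.41 ± 0.06. G1/S genes had 9 members up, 2 down and 13 not called, or 12 and 2 when adjusted over the list alone (median 0.18, adjusted p = 0.0077, and adjusted p = 0.383 with an estimated correlation), with CDC21 at 0.56 ± 0.07. G2/M genes had 9 members down, 1 up and 4 not called, or 10 and 1 when adjusted over the list alone (median -0.36, adjusted p = 0.000727, and adjusted p = 0.445 with an estimated correlation), with CDC20 at -0.66 ± 0.07. M/G1 genes had 9 members down, 0 up and 5 not called, or 9 and 0 when adjusted over the list alone (median -0.41, adjusted p = 0.000646, and adjusted p = 0.445 with an estimated correlation), with PCL9 at -1.01 ± 0.07. Chaperone genes had 15 members down, 2 up and 8 not called, or 16 and 2 when adjusted over the list alone (median -0.31, adjusted p = 0.000727, and adjusted p = 0.383 with an estimated correlation). HSP104 fell (-1.29 ± 0.13) and HSP42 (-1.45 ± 0.13).

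Ribosomal protein genes had 21 members down, 2 up and 111 not called, or 16 and 2 when adjusted over the list alone (median -0.14, adjusted p = 7.77e-05, and adjusted p = 0.731 with an estimated correlation). Sulfur genes had 8 members down, 1 up and 14 not called, or 9 and 1 when adjusted over the list alone (median -0.26, adjusted p = 0.0237, and adjusted p = 0.666 with an estimated correlation), and SAM2 was 2.82-fold lower. This call was lost without wild type replicate 2 (adjusted p = 0.0809). Chromosome-end genes had 27 members down, 12 up and 86 not called, or 29 and 12 when adjusted over the list alone (median -0.17, adjusted p = 0.0237, and adjusted p = 0.445 with an estimated correlation). Their call was lost without wild type replicate 2 or W81A replicate 1 (adjusted p = 0.0791 and 0.0717). DNA damage genes had no list call (3 higher and 4 lower of 20, or 5 and 4 when adjusted over the list alone, median -0.0277, adjusted p = 0.985), with RNR1 at 0.56 ± 0.07. The proteasome had no call (2 higher and 1 lower of 32, or 0 and 0 when adjusted over the list alone, median -0.0501, adjusted p = 0.522), nor had general stress (10 higher and 10 lower of 29, or 11 and 12 when adjusted over the list alone, median 0.0798, adjusted p = 0.985). There were 1611 calls, 753 up and 858 down, and 2840 genes with non-overlapping groups, with 10% by chance. On chromosome XII, shifted by 0.00278 as a set, 28 were up and 40 down.

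The TAF14 strain against wild type showed how far the plasmid-borne gene departed from the chromosomal one. PRM7 was 7.44-fold higher (398 ± 244 against 53.4 ± 11.8 CPM, 2.90 ± 0.39) and SNZ1 6.40-fold lower (32.0 ± 4.93 against 205 ± 18.5 CPM, -2.68 ± 0.12). PHO5 was 4.03-fold lower (27.5 ± 4.28 against 111 ± 29.2 CPM, -2.01 ± 0.18), and SPO19, perhaps from the plasmid, was higher by 6.63 ± 0.47. BSC1 rose by 2.50 ± 0.40, SER3 by 1.82 ± 0.23, the kynurenine-pathway gene BNA2 by 1.67 ± 0.24 and the ferric reductase gene FRE4 by 1.55 ± 0.29, and HSP26 was 3.49-fold higher. CIP1 fell (-2.02 ± 0.26), the glycine decarboxylase gene GCV2 (-1.75 ± 0.24) and ARO5 (-1.49 ± 0.08).

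Of 32 respiratory-chain and ATP synthase genes, 22 fell, 0 rose and 10 were not called, or 26 and 0 when adjusted over the list alone (median -0.41, adjusted p = 7.32e-13, and adjusted p = 0.203 with an estimated correlation). The NADH dehydrogenase gene NDI1 fell (-0.70 ± 0.09). Amino acid genes had 17 members down, 1 up and 21 not called, or 21 and 2 when adjusted over the list alone (median -0.24, adjusted p = 1.58e-07, and adjusted p = 0.203 with an estimated correlation), with LYS1 at -1.40 ± 0.08. PHO genes had 10 members down, 1 up and 5 not called, or 13 and 2 when adjusted over the list alone (median -0.68, adjusted p = 1.58e-07, and adjusted p = 0.203 with an estimated correlation), with SPL2 at -2.30 ± 0.28. M/G1 genes had 8 members down, 0 up and 6 not called, or 9 and 0 when adjusted over the list alone (median -0.45, adjusted p = 2.66e-06, and adjusted p = 0.203 with an estimated correlation). EGT2 fell (-0.64 ± 0.07). Histones had 7 members down, 0 up and 4 not called, or 9 and 0 when adjusted over the list alone (median -0.30, adjusted p = 0.000664, and adjusted p = 0.357 with an estimated correlation). HTB2 fell (-0.36 ± 0.06). General stress genes had 9 members down, 2 up and 18 not called, or 10 and 2 when adjusted over the list alone (median -0.32, adjusted p = 0.000766, and adjusted p = 0.378 with an estimated correlation), with SPI1 at -1.26 ± 0.14. G1/S genes had 4 members down, 0 up and 20 not called, or 4 and 0 when adjusted over the list alone (median -0.13, adjusted p = 0.0018, and adjusted p = 0.203 with an estimated correlation), with MCD1 at -0.32 ± 0.06.

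Of 17 glycolysis genes, 14 rose, 1 fell and 2 were not called, or 14 and 1 when adjusted over the list alone (median 0.48, adjusted p = 4.02e-09, and adjusted p = 0.203 with an estimated correlation). GPM1 rose by 0.61 ± 0.07 and FBA1 by 0.70 ± 0.10. Ribosome biogenesis genes had 17 members up, 0 down and 36 not called, or 29 and 0 when adjusted over the list alone (median 0.16, adjusted p = 2.15e-10, and adjusted p = 0.203 with an estimated correlation). NSR1 rose by 0.34 ± 0.06. Ribosomal protein genes had 10 members up, 0 down and 124 not called, or 2 and 0 when adjusted over the list alone (median 0.16, adjusted p = 5.49e-09, and adjusted p = 0.537 with an estimated correlation). RNA polymerase I and III genes had 4 members up, 0 down and 15 not called, or 5 and 0 when adjusted over the list alone (median 0.14, adjusted p = 6.8e-05, and adjusted p = 0.203 with an estimated correlation). Proteasome genes had 6 members up, 0 down and 26 not called, or 12 and 0 when adjusted over the list alone (median 0.14, adjusted p = 2.81e-06, and adjusted p = 0.331 with an estimated correlation). PRE7 rose by 0.50 ± 0.05. Ergosterol genes had 8 members up, 1 down and 17 not called, or 11 and 1 when adjusted over the list alone (median 0.17, adjusted p = 0.000145, and adjusted p = 0.203 with an estimated correlation), with ERG3 at 0.56 ± 0.07. Drug efflux genes had 5 members up, 0 down and 3 not called, or 6 and 0 when adjusted over the list alone (median 0.40, adjusted p = 0.00927, and adjusted p = 0.203 with an estimated correlation), with TPO1 at 0.77 ± 0.13.

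The 4 list calls with the highest adjusted p depended on single libraries. Oxidative stress had 3 members up, 0 down and 12 not called, or 4 and 0 when adjusted over the list alone (median 0.26, adjusted p = 0.0231, and adjusted p = 0.493 with an estimated correlation). The call was lost without wild type replicate 3, replicate 1 of the TAF14 strain or chromosome XII genes (adjusted p = 0.111, 0.0696 and 0.057). G2/M genes had 3 members up, 0 down and 11 not called, or 3 and 0 when adjusted over the list alone (median 0.0945, adjusted p = 0.0343, and adjusted p = 0.561 with an estimated correlation), and CLB2 rose by 0.62 ± 0.08. The list call was lost without wild type replicate 2, or replicate 1 or 3 of the TAF14 strain (adjusted p = 0.217, 0.0729 and 0.0569). The unfolded protein response had 1 member up, 0 down and 9 not called, or 1 and 0 when adjusted over the list alone (median 0.14, adjusted p = 0.0343, and adjusted p = 0.378 with an estimated correlation). The call was lost without the same 3 libraries (adjusted p = 0.0513, 0.166 and 0.107). Inositol and phospholipid genes had 5 members down, 0 up and 11 not called, or 7 and 0 when adjusted over the list alone (median -0.0441, adjusted p = 0.0372, and adjusted p = 0.493 with an estimated correlation). The call was lost without wild type replicate 1 or 2, replicate 1 or 3 of the TAF14 strain, or chromosome XII genes (adjusted p = 0.057, 0.106, 0.133, 0.070 and 0.057). The pheromone list was not called (5 higher and 0 lower of 21, or 6 and 0 when adjusted over the list alone, median 0.11, adjusted p = 0.0511). The DNA damage list was not called (3 higher and 5 lower of 20, or 3 and 5 when adjusted over the list alone, median 0.0831, adjusted p = 0.715).

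There were 998 calls against wild type, 480 up and 518 down, and 1980 genes with non-overlapping groups, with 10% by chance. With upper-quartile scaling the higher share moved from 48.1% to 36.4%, with 360 up and 628 down. With DESeq2 it was 55.3% (570 up, 461 down) and with relative log expression scaling 52.9% (537 up, 479 down), so the balance of directions was not settled. Leaving out replicate 2 of the TAF14 strain gave 1385 calls. Leaving out wild type replicate 1 gave 559, wild type replicate 3 gave 636, and replicates 1 and 3 of the TAF14 strain gave 660 and 655. On chromosome XII, shifted by 0.236 as a set, 81 were up and 6 down, and without replicate 2 of the TAF14 strain 65 were up and 47 down.

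The W81A against TAF14 and deletion against wild type comparisons share no libraries, and their changes were compared across tested genes. The correlation was r = 0.358, and 0.364 without TAF14 and SPO19. Genes called up in both numbered 323, against 225 expected if calls were independent (Fisher's exact p = 1.87e-15). Those called down in both numbered 452, against 253 (Fisher's exact p = 5.31e-52). These p-values count correlated genes as independent and are descriptive only. Opposite calls were fewer, with 158 up then down against 233 expected and 181 down then up against 244. BAR1 fell in both (-3.22 ± 0.18 and -3.15 ± 0.19), and so did CDC5 (-0.64 ± 0.07 and -0.71 ± 0.07). Opposite calls were found among proteasome genes, with PRE7 at -0.32 ± 0.05 and 0.76 ± 0.05. Chromosome XII was shifted by -0.221 in the first and 0.508 in the second, and r was 0.417 without it.

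**Figure D4:**
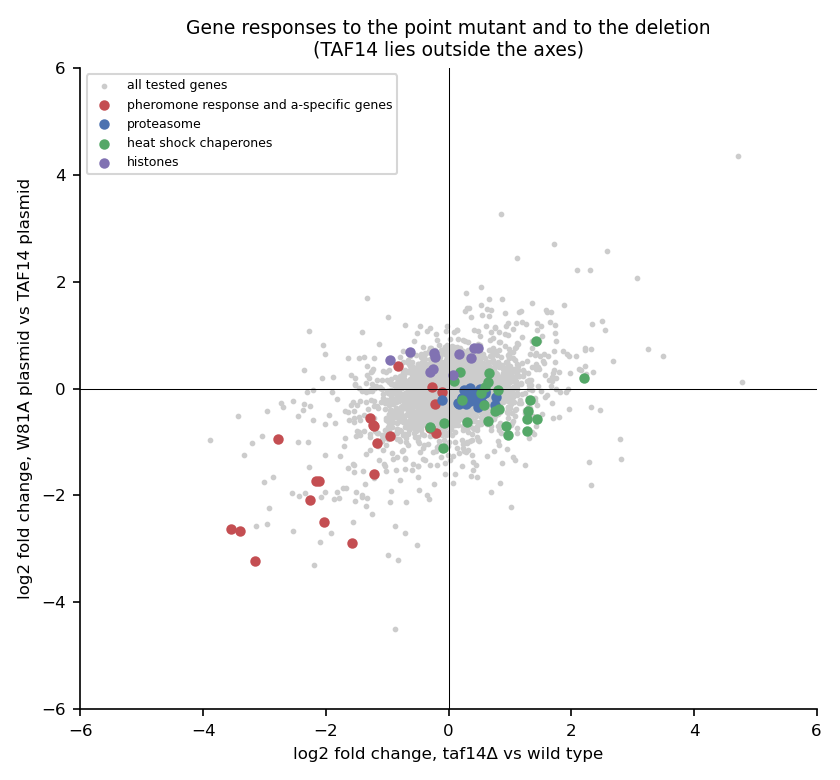
Log2 fold change of each gene in the W81A strain against the TAF14 strain and in the deletion strain against wild type, with 4 lists marked and TAF14 outside the axes.

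**Figure D5:**
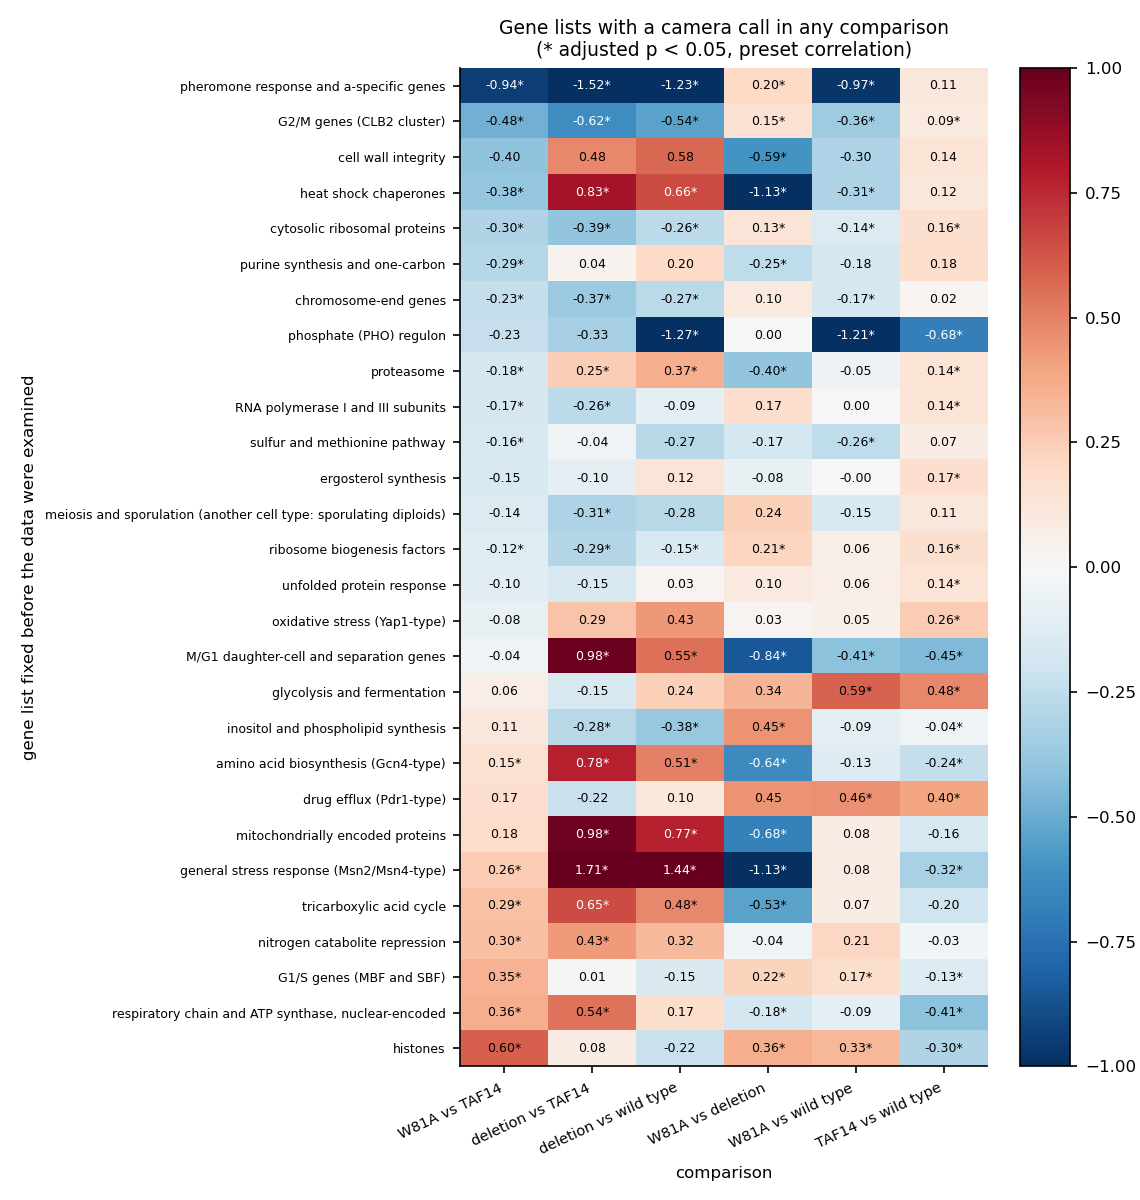
Median log2 fold change of each list in the 6 comparisons, with an asterisk where camera's adjusted p was below 0.05 at the preset correlation. Pheromone-response genes had a median of -1.52 in the deletion strain against the TAF14 strain.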

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

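The alternatives were listed before the data were examined, except leaving out chromosome XII, chosen after seeing them. No called list and no called named gene changed direction. Of the total counts and correlations, 168 values under alternatives stayed within the set limit of the reported value and 23 moved. The balance of up and down calls turned in 5 of 6 comparisons, under more settings than named here. It turned in the W81A strain against the TAF14 strain from 938 and 1016 to 1028 and 896 with upper-quartile scaling. In the deletion strain against wild type it went from 1420 and 1471 to 1432 and 1350 with DESeq2, and in the TAF14 strain against wild type from 480 and 518 to 570 and 461. In the deletion strain against the TAF14 strain it went from 1428 and 1465 to 1455 and 1424 with upper-quartile scaling, and in the W81A strain against the deletion strain from 1343 and 1334 to 1253 and 1332 with DESeq2. Of the log2 fold changes of named genes, 13427 stayed on the same side of the threshold and 448 lost their call.

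At a 2-fold limit, which removes smaller changes by construction, 200.0 genes were called in the W81A strain against the TAF14 strain (64 up, 136 down). The deletion strain had 408 against the TAF14 strain (209 up, 199 down) and 366 against wild type (193 up, 173 down). The TAF14 strain had 96 against wild type (56 up, 40 down), and the W81A strain 281 against the deletion strain (88 up, 193 down) and 177 against wild type (55 up, 122 down). In that order camera called 17, 17, 14, 18, 17 and 12 lists at its preset correlation. With it estimated, 0, 0, 0, 0, 1 and 0 were called.

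Leaving out 1 library gave 1446 to 2149 genes in the W81A strain against the TAF14 strain, and 2509 to 3165 and 2461 to 2808 in the deletion strain against the TAF14 strain and wild type. The W81A strain had 2225 to 2485 against the deletion strain and 1197 to 1375 against wild type. For the TAF14 strain against wild type the range was 559 to 1385, and a fit of those 6 libraries alone gave 432. The correlation of the W81A change with the deletion change ranged from 0.312 to 0.394, was 0.417 without chromosome XII and 0.293 for W81A against wild type with deletion against TAF14. Neither cause was tested.

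In the order W81A against TAF14, deletion against TAF14, deletion against wild type, TAF14 against wild type, W81A against deletion and W81A against wild type, DESeq2 gave 1877, 2792, 2782, 1031, 2585 and 1558 genes. In the same order limma-voom gave 1946, 2917, 2908, 981, 2680 and 1607. A replicate term gave 1915, 2907, 2872, 942, 2647 and 1599 genes. Correlations of same-numbered libraries between groups, after group means were removed, ran from -0.219 to 0.309 in 18 pairs, with 3 above 0.1. Because 0 libraries matched their own number best in all other groups, numbers were not treated as pairs. At this depth and with 3 libraries per group, the smallest simulated changes were recovered in 33.6% of cases, those of 1.5-fold in 86.0% and those of 2-fold in 99.2%, with 5.34% false calls.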

Other observations

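Retrotransposon genes were chosen after values were seen, and no list test was set for them. Of 91 annotated gag and gag-pol genes 31 were tested, and their median near copy covered 100% of the gene, so single genes are uncertain and not independent. Summed expression was 561.6 ± 52.2 CPM in wild type, 227 ± 44.2 in the deletion strain, 1005 ± 349 in the TAF14 strain and 354 ± 16.5 in the W81A strain (n = 3 each). Replicate 2 of the TAF14 strain had 619 CPM, and the other 2 had 1297 and 1100.0. In the W81A strain against the TAF14 strain 26 genes fell and 2 rose (median -1.74), and in the deletion strain 25 fell and 0 rose (median -2.12). Against wild type, 17 fell and 1 rose in the deletion strain (median -1.34), 15 fell and 1 rose in the W81A strain (median -0.71), and 17 rose and 0 fell in the TAF14 strain (median 0.82).

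Regrouping of libraries was set before the data were examined. The 6 libraries of a comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1954, 2893, 2891, 998, 2677 and 1611 genes, in the order used above. The highest other split gave 2 genes in the first and 0 in the rest with edgeR, so 1 of 10 splits reached the real count each time, and at unadjusted p < 0.05 the highest others were 581, 858, 608, 893, 244 and 356. For lists, the real counts of 17, 17, 14, 18, 17 and 12 stood against 21, 16, 13, 19, 15 and 11, and 3, 1, 1, 3, 1 and 1 of 10 splits reached the real count. Every other split mixes the groups, so their difference enters its spread and partly remains. Its gene and list counts are no chance level.

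For the chromosome XII shift, the tests of a second copy were chosen after the result was seen, and those of a single region and of base composition before. The lowest of 11 bins of 100 kb had a median of 0.393 in the deletion strain against wild type, so no single region carried the shift. The trend with GC content and gene length elsewhere gave a shift of 0.0039. The highest upper limit in a library was 0.594, below the doubling that a second copy in every haploid cell with expression in proportion would give. A second copy in part of the cells would need up to 48.7% of them. RNA cannot tell this from a partly compensated copy or an extra copy in diploid cells.

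All 3 tests on replicate 2 of the TAF14 strain were chosen after the result was seen. Genes at least 4-fold higher in the deletion strain gave a median of 4.5% admixture of deletion cells, and chromosome XII would need 116%. A swap with a wild type library does not account for SPO19, at 35.5 times the highest wild type library. TAF14, SPO19 and HIS3 were at 0.434, 0.352 and 0.498 of the mean of replicates 1 and 3, but these values are what set the library apart, so they do not test for less plasmid. They leave its HSP12 and chromosome XII differences open, and no biological explanation was tested.

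For the lower mating genes, the tests of alpha cells and of chromosome XII were chosen after the result was seen. Those of diploid cells and base composition were written before they were run, but the haploid-specific genes were chosen after values were seen. The highest MF(ALPHA)1 value in a W81A library was 0.2 CPM, which leaves little room for alpha cells. Haploid-specific genes, which a/alpha diploid cells would lack, had a median of -0.0742 in the W81A strain against the TAF14 strain, where STE4 fell (-0.80), STE12 fell (-0.60) and AXL1 fell (-0.56). Removing the trend with GC content and gene length left the list at -0.905, and the chromosome XII shift was 0.00278 in the W81A strain against wild type. These tests cover the W81A strain, since the haploid-specific median was -0.587 in the deletion strain against wild type.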
